A study of Mus musculus with 2 samples.

How the data were processed

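Chromatin from the heart ventricles of 15-week-old wild-type mice was fixed with 2% formaldehyde, sheared and immunoprecipitated with an antibody against TBX5, a T-box transcription factor, or with a rabbit IgG as a control for unspecific pull-down. The DNA was sequenced (ChIP-seq). The series' design text gives 2 biological replicates for each antibody. The data used here are 1 list of merged TBX5 peaks. No list or read count of the IgG sample was used here, and no value of a single replicate was analysed here, so no spread between replicates stands behind any value below and every test describes this list of peaks only.

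Per the submitters' processing notes, FastQC 0.10.0, Bowtie2 2.2.6.2, MACS2 2.1.1.20160309.0 and the mouse build mm9 were used. The caller's settings, its control library, its treatment of duplicate reads and the way replicates were merged are not given in the sources used here. The deposited list has the 10 columns of a MACS2 narrowPeak file. For each peak it holds a start and end, a summit, a fold enrichment over the local background (a ratio), −log10 p, −log10 q and a score. The deposited score was the whole part of 10 times the deposited −log10 q in 8846 of 8849 peaks. The lowest −log10 q was 1.30, which is a q of 0.05. Each −log10 p went with 1 −log10 q, as in a list from a single run of the caller on pooled reads. The caller's peak numbers ran to 8922. The peaks of 73 numbers missing from the list, at 68 places and none of them on X, were not analysed here, and only their number per chromosome entered an alternative count. Peak scores, folds and −log10 values are the authors', and coordinates are given on mm9, counted from 1.

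The only annotation at hand was a gene table of assembly GRCm38.p6. Of the peaks, 76 on 7 chromosomes lay beyond the last gene of their chromosome in that table, so the builds differ and no peak was assigned to a gene. The planned comparisons of peaks with promoters and introns, with fixed gene lists (conduction, calcium handling, sarcomere, other cell types), between such lists, and with T-box and partner motifs need an mm9 genome and were not run. Apart from this check, the table served only to count protein-coding genes per chromosome.

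The fragments behind each peak were computed from the deposited fold and −log10 p. At a summit, MACS2 gives fold = (scaled TBX5 pileup + 1) / (local control level + 1) and the upper Poisson tail of that pileup. The local control level is the highest of the control pileup at the summit, the averages over 1 kb and 10 kb, and the genome background. A single scale of 0.787 and a genome background of 1.18 fragments per position solved all 8849 peaks for a whole number of TBX5 fragments. The largest difference from the deposited −log10 p was 0.00016, with a tolerance of 0.005 on −log10 p and 0.002 on the control level. A second solution lay within that tolerance for 102 peaks, for which the closer one was taken. Control levels above the background fell, within the tolerance, on whole numbers or on the steps that averages over 1 kb and 10 kb take with a fragment length of 125 bp, which was also the narrowest peak. A whole-number level was counted as set by the summit window, although a 1 kb window gives one too at every eighth count. The control is called the control library below, since the sources used here do not say that it was the IgG sample, the only control the labels name. With the caller's preset mouse genome size of 1.87e9, which is an assumption here, the background gives 17.6 M control reads and 22.4 M TBX5 reads (M, 1e6). The recovery was tested on simulated data (6069 and 7550 peaks in 2 simulations with other scales and backgrounds), where both numbers came back right for 100% of peaks.

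Intervals on fragments are exact 95% Poisson intervals. They cover counting error only, and reads without molecular identifiers are not independent molecules. Peaks per Mb used the span from the first to the last peak of a chromosome. Peak numbers per chromosome were set against 1000 random placements over these spans. The plan had these placements over a genome of the files' build, which was not at hand. The spans, taken from the peaks themselves, depart from that plan. Peaks within 12.5 kb of each other were stitched into clusters, and the number of clusters of 3 or more was set against 1000 placements with the same chromosomes and widths, over the whole span or within each peak's own 1 Mb window. Placements did not exclude assembly gaps or repeats. In simulated data of 3000 evenly placed peaks the cluster test called 20 of 20 runs with 200 planted groups and 0 of 20 runs without. Relations across peaks are Spearman's rho with a 2-sided permutation test (100000 resamples, 5 relations, Benjamini-Hochberg adjusted). The 2 relations of TBX5 fragments with the control level were computed outside these 5 and are unadjusted. Peaks are not replicates. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

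The items named in the text were fixed before the data were examined: the 10 peaks with the highest score and the 5 clusters with the most peaks. Peaks singled out beyond these (the highest control levels, the most fragments, the strongest on X) were chosen after their values were seen. So were the clusters named behind the 5 largest, the fullest 1 Mb windows and the longest gaps. The alternative settings fixed then were the higher-scoring peaks alone (at or above the median −log10 q), peaks within 1 kb merged, leaving out contigs and Y, a stitching distance of 5 kb, and peak width in place of score as the rank. The shares set to be followed along that rank were those of promoters, motifs and gene lists, which were not run. The count of peaks per gene was planned for the chromosomes, but its use for the gap to X was added after seeing the data. So were the placements within 1 Mb windows and over autosomes alone, and the missing peak numbers. The relations of score with width, control level and clustering, computed in place of those shares, were also added then. The same holds for the analysis of control levels with its checks on peaks of a single solution and on higher-scoring peaks.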

Results

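The TBX5 peak list held 8849 sites in adult mouse ventricle chromatin that covered 2095 kb. TBX5 is a T-box transcription factor required for heart development, and the study asks where it is bound in the adult ventricle. Of the sites, 8739 lay on chromosomes 1 to 19 and 102 on X. The remaining 8 were 1 peak on Y and 7 peaks on random or unplaced contigs. Peaks were narrow, with a median width of 202 bp (range 125 to 1178 bp), and the summit lay near the middle, at a median of 49.2% of the width. The median fold over the local background was 5.52 and the range was 1.88 to 44.9. A fold of 10 or more was reached by 1210 peaks (13.7%), and 557 peaks (6.29%) were below 3. The summit of a median peak rested on 32 TBX5 fragments, with a range of 9 to 230.

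The highest-scoring TBX5 site was on chromosome 2 from 26975806 to 26976260, with 199 TBX5 fragments at its summit (95% Poisson interval 172 to 229) over a control level of 2.62, a fold of 43.5. The second lay on chromosome 16 from 90921505 to 90922068, with 210 fragments (183 to 240) and a fold of 33.2. A site on chromosome 17 from 73575242 to 73575719 was next in score and had the highest fold of the list, 44.9, from 170 fragments (145 to 198) over a control level of 2. The fourth, on chromosome 6 from 142638194 to 142638606, had a fold of 37.6. The fifth, on chromosome 16 from 5431083 to 5431790, had a fold of 26.5. The 6th to 10th sites were on chromosome 8 (35103402 to 35103904, fold 34.7), chromosome 5 (113361988 to 113362539, fold 44.1), chromosome 1 (94240245 to 94240770, fold 31.2), chromosome 13 (12225634 to 12226451, fold 28.2) and chromosome 8 (94511798 to 94512231, fold 20.7). These 10 sites were 413 to 818 bp wide and held 146 to 210 TBX5 fragments, and sites next to each other in score had overlapping fragment intervals. With the control level held fixed, the counting error alone put the fold of the chromosome 2 site between 37.7 and 49.9 and that of the chromosome 17 site between 38.5 and 52.1. The interval of the second site, 28.9 to 38.0, lay below the latter. These intervals leave out the counting error of the control level, which was 4 at the second site and 2 at the chromosome 17 site. The order of these folds is therefore not settled. No mm9 annotation was used here, so the genes at these sites are not named.

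The comparison of TBX5 with the control library asks how far each site stands above a control, which the sources used here do not name. The local control level, the highest of several windows, lay above the genome background of 1.18 fragments per position at 91.4% of TBX5 sites, against 73.9% of sites simulated with evenly spread control reads. Its median was 3.5 at the TBX5 sites and 1.38 at the even sites. A level of 3 or more was found at 5695 peaks (64.4%), against 11.7% of the even sites. A level of 5 or more was found at 3157 peaks (35.7%), against 0.7% of them. The control pileup at the summit itself set the level at 5388 peaks (60.9%), the 1 kb average at 2142 (24.2%), the 10 kb average at 560 (6.33%) and the genome background at 759 (8.58%). The fold has the control level in its denominator and falls with it by construction. The median fold was 3.02 for the 653 peaks at a level of 10 or more and 2.41 for the 20 peaks at 20 or more.

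**Figure D1:**
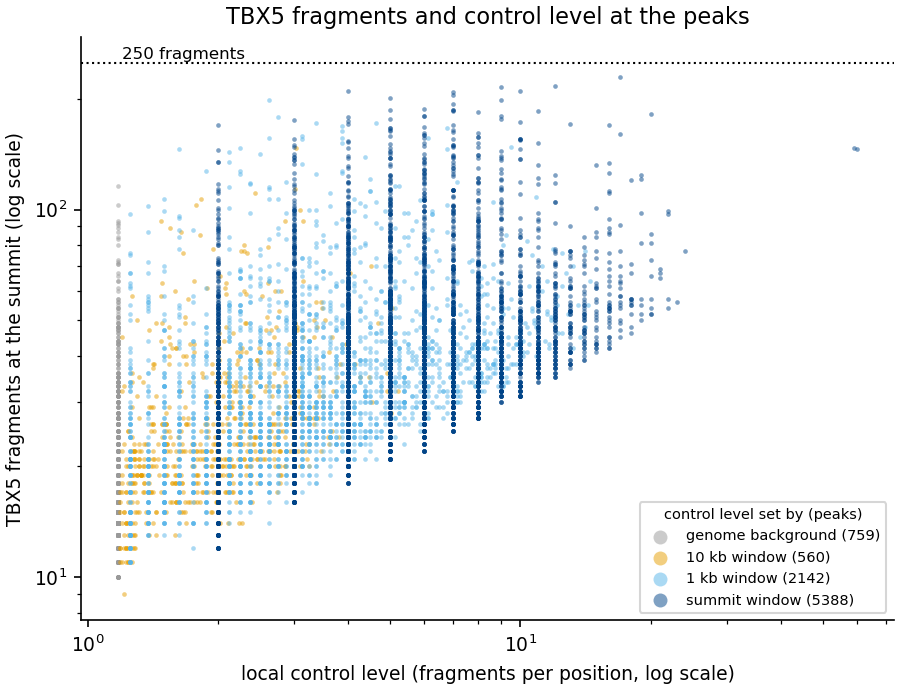
TBX5 fragments at the summit (y, log scale) against the local control level (x, fragments per position, log scale) for the 8849 peaks, coloured by what set the control level; the dotted line marks 250 fragments. The lower edge rises with the control level, the highest point has 230 fragments, and 2 peaks stand apart at control levels of 59 and 60.

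A pair of adjoining sites on chromosome 14 had by far the most control reads. The peak from 55585459 to 55585936 had a control level of 59 and 147 TBX5 fragments (124 to 173), a fold of 1.94. The peak from 55586426 to 55587052 had a control level of 60 and 146 TBX5 fragments (123 to 172), a fold of 1.90. The next highest control level was 24, at a chromosome 19 peak from 54018537 to 54018728 with a fold of 2.46. The most TBX5 fragments, 230 (201 to 262), were at a chromosome 17 peak from 73371708 to 73372413. Its control level of 17 left it at a fold of 10.1. Across peaks, which are not replicates, TBX5 fragments and control level rose together (rho = 0.58, permutation p = 1e-05, the smallest the permutations can give). A site enters the list only if its TBX5 fragments pass a threshold over that same control level. Sites with few fragments over a high control are therefore absent, and a positive rho arises in part from this selection. The permutation p does not separate the 2. Among the 1174 peaks with 60 or more TBX5 fragments and a control level up to 20, rho was 0.0068 (permutation p = 0.8). Keeping only the top of the fragment range can itself lower rho, so this value does not show how much of the 0.58 came from selection. A site of 60 fragments over a control level of 20 has a −log10 p of 7.11, above the lowest −log10 p in the list of 4.22.

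TBX5 peaks were spread over all autosomes and were sparse on X. The 19 autosomes carried 3.74 ± 0.548 peaks per Mb (SD over chromosomes). Chromosome 14 was the lowest of them, with 326 peaks and 2.81 per Mb. Chromosome 11 was the highest, with 569 peaks and 4.80 per Mb. Chromosome X carried 102 peaks, 0.644 per Mb (95% Poisson interval 0.525 to 0.782), which was 4.36-fold below chromosome 14 and 5.81-fold below the autosomal mean. Random placement put 553.9 ± 22.7 peaks (SD) on X. Of the 20 chromosomes, 8 held more peaks than placed and 3 fewer (3, 14 and X) at an adjusted permutation p under 0.05. Because X held few peaks, these placements put fewer peaks on the autosomes than were there in total. With autosomal peaks placed over autosomes alone, 6 held more (8, 9, 11, 17, 18 and 19) and 5 fewer (1, 3, 6, 12 and 14) at that threshold. All these placements treat peaks as independent, whereas TBX5 peaks gathered in groups. The placed SDs are therefore too small and the permutation p-values too low. For X the adjusted permutation p over the 20 chromosomes was 0.005, the smallest that 1000 placements and 20 chromosomes gave here. Counted per protein-coding gene of the GRCm38.p6 table, X had 0.106 peaks and the autosomes 0.262 to 0.704, with chromosome 7 the lowest and chromosome 18 the highest.

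**Figure D2:**
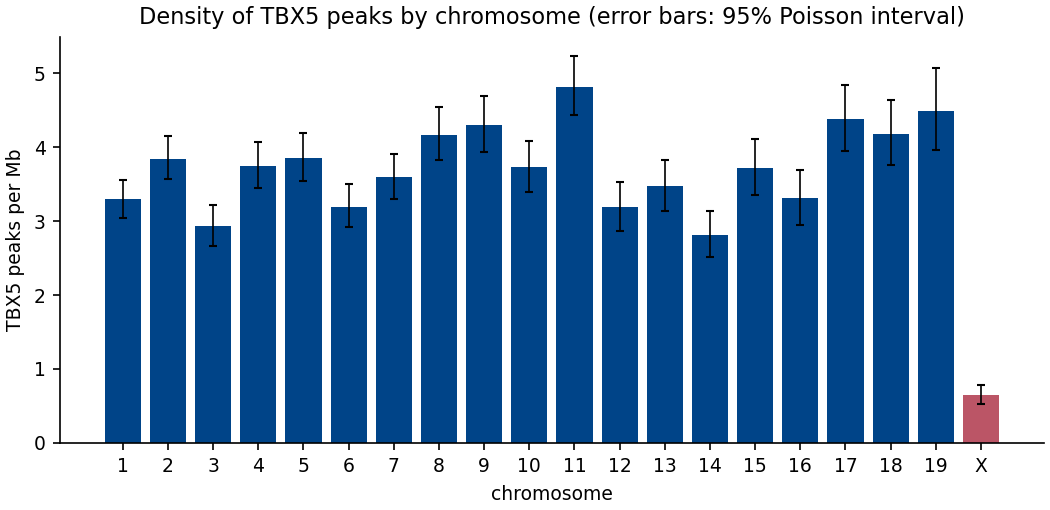
TBX5 peaks per Mb (y) for chromosomes 1 to 19 and X (x); bars are the peak number over the span from first to last peak, and error bars are 95% Poisson intervals, which cover counting error only. The autosomes lie between 2.81 and 4.80 per Mb and X at 0.644.

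The peaks that were on X were shallower but had no lower median fold, a comparison that was not tested. Their summits held a median of 23 TBX5 fragments over a control level of 1.75, against 32 fragments over 3.5 on the autosomes. The median fold was 6.36 on X and 5.51 on the autosomes, where chromosome medians ran from 5.08 to 5.84. A site over a low control level needs fewer fragments but a higher fold to enter the list. In the whole list, peaks at the genome background had a median fold of 6.61 on 17 fragments. Peaks whose level the summit window set had 4.89 on 36. The higher median fold on X therefore does not show stronger binding there. The strongest X site, from 156380445 to 156380869, had 106 fragments (86.8 to 128) and a fold of 28.1. Of the 160 windows of 1 Mb on X, 108 held no peak. The longest stretch without a peak in the list was on X from 104035191 to 124324984 (20.3 Mb), and the longest on an autosome was on chromosome 1 from 110468887 to 120207792 (9.74 Mb).

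TBX5 peaks gathered in groups. At the stitching distance fixed beforehand, 3232 of the 8841 peaks on chromosomes 1 to 19 and X (36.5%) had a neighbour, in 1300 groups, and 374 groups held 3 or more peaks. On average, 797.5 peaks had a neighbour under random placement over the chromosomes and 1488 under placement within 1 Mb windows. Random placement over the chromosomes gave 18.3 ± 4.2 groups of 3 or more (SD, 1000 placements), 20.5-fold fewer (permutation p = 0.002, the smallest possible). Placement of each peak within its own 1 Mb window, which keeps the regional density, gave 81.2 ± 7.98 such groups, 4.61-fold fewer (permutation p = 0.002). The excess of neighbouring summits was largest at the shortest distances. Neighbouring summits under 1 kb apart numbered 401, 6.31-fold the number from placement within windows. Those 1 to 5 kb apart numbered 750 (2.93-fold) and those from 5 kb to the stitching distance 761 (1.68-fold). Groups and spacing were not recounted with peaks within 1 kb merged. Pairs under 1 kb apart may thus be parts of 1 enriched region, and group sizes count each called peak. From the stitching distance to 50 kb the 1860 pairs were 1.02-fold the placed number, with no difference past the threshold (permutation p = 0.25). Only next neighbours are paired, so an excess of near pairs leaves fewer far ones. The 1.02 therefore does not show where the excess ends.

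**Figure D3:**
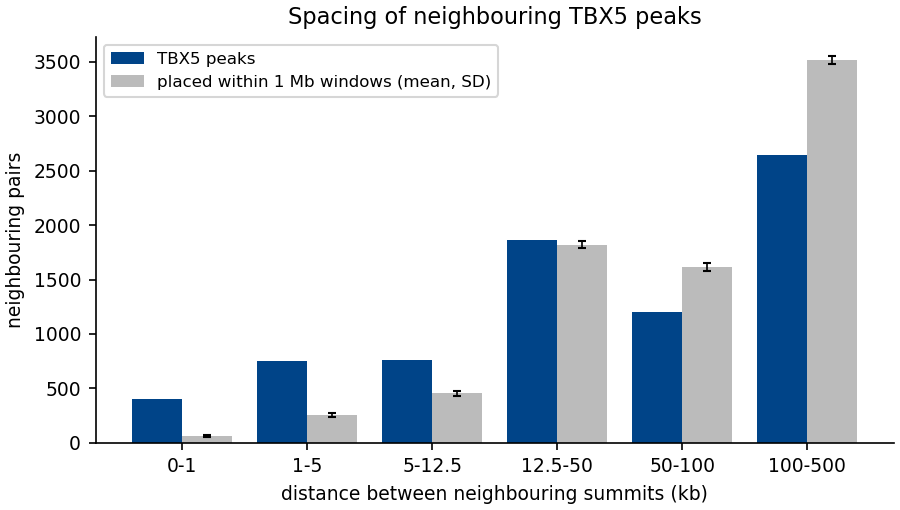
Number of neighbouring TBX5 summit pairs (y) by their distance in kb (x), for the peaks and for 1000 placements of each peak within its own 1 Mb window (mean, error bars SD). Pairs within the stitching distance exceed the placed number, and pairs from 50 to 500 kb fall below it. Only next neighbours are paired, so an excess of near pairs leaves fewer far ones.

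The largest group was on chromosome 11 from 98235651 to 98256720, with 12 peaks in 21.1 kb, and its folds ran from 2.67 to 13.5. A group on chromosome 5 from 23826388 to 23858685 held 11 peaks in 32.3 kb, with up to 146 TBX5 fragments at a summit. Groups of 9 peaks lay on chromosome 15 from 25844767 to 25893603 (highest fold 17.5), on chromosome 6 from 101257924 to 101324949 (highest fold 14.4) and on chromosome 1 from 74045165 to 74064653 (highest fold 7.79). In placements within windows the largest group of any run had 9 peaks. Of the 2551 windows of 1 Mb, 765 held no peak, against 161 ± 8.65 under random placement over chromosomes. The fullest window, on chromosome 1 from 74 to 75 Mb, held 28 peaks, and 29 windows held more than the 17 peaks of the fullest window in any placement. The next fullest were on chromosome 8 from 129 to 130 Mb with 25 peaks and on chromosomes 7 (56 to 57 Mb), 13 (12 to 13 Mb) and 19 (53 to 54 Mb) with 24 each.

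**Figure D4:**
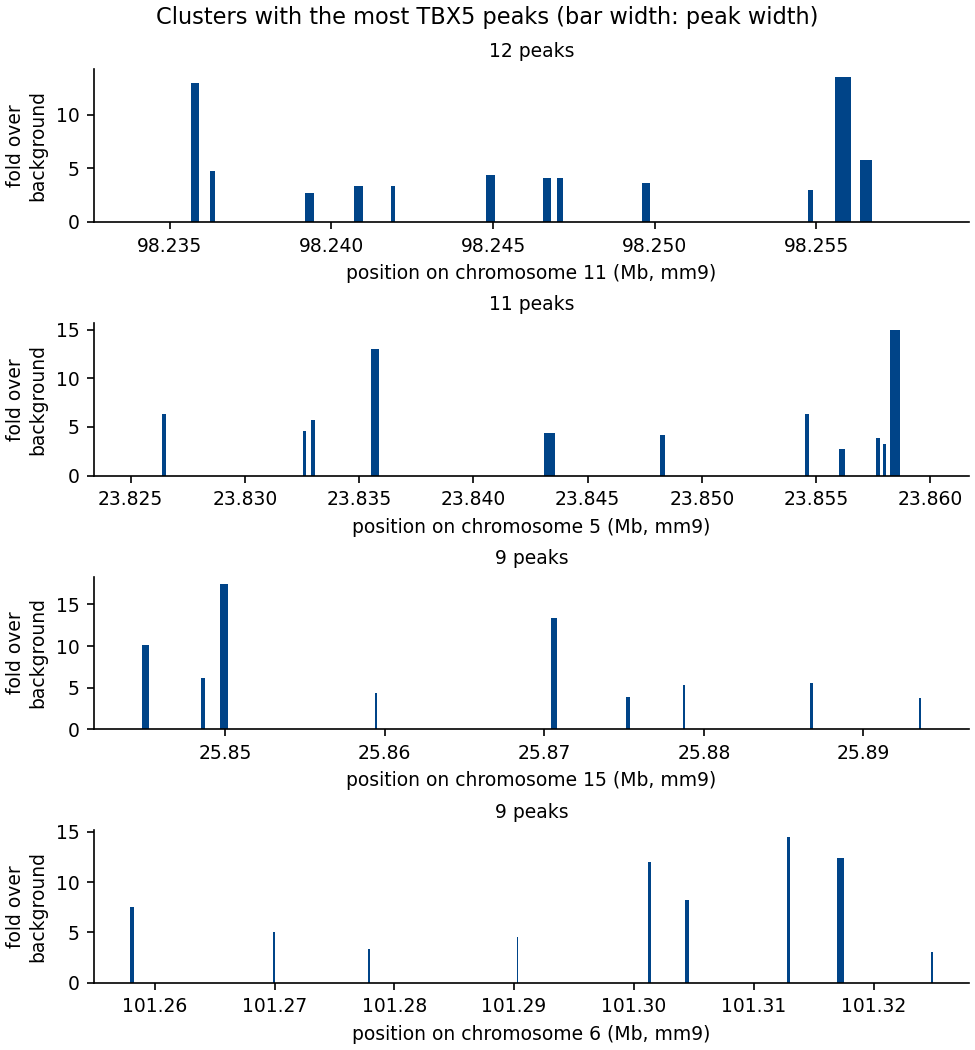
Of the 5 groups with the most TBX5 peaks, the 4 on chromosomes 11, 5, 15 and 6 (the group on chromosome 1, tied at 9 peaks with those on 15 and 6, is not drawn); x is the mm9 position in Mb, and each bar has the width of its peak and the height of its fold over the local background. Strong peaks of a group stand beside weaker ones, with folds from 2.67 to 13.5 in the chromosome 11 group.

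Stronger peaks were wider, and the highest-scoring ones were slightly more often grouped. Score, width and fragments come from the same pileup, so a higher peak is also wider by construction. In 4 groups of about equal size by score, from lowest to highest, the median width was 157, 170, 206 and 316 bp, and the median TBX5 fragments at the summit were 23, 26, 33 and 59. Score and width were related across peaks (rho = 0.59, permutation p = 1e-05, adjusted 1e-05). The share of peaks with a neighbour was 34.5% in the lowest-scoring group (95% Wilson interval 32.6 to 36.5), 36.3% and 35.5% in the middle groups and 39.9% in the highest-scoring (37.8 to 41.9). Across all peaks rho was 0.036 (permutation p = 0.0007, adjusted 0.0007). Neighbouring peaks share their membership, while these intervals and this permutation treat peaks as independent, so they overstate the precision. Score and control level had only a weak rank relation (rho = -0.067, permutation p = 1e-05, adjusted 1e-05), and the sign turned to rho = 0.17 when peaks were ranked by width. The median control level in the 4 score groups was 4, 3.03, 3 and 3.51, from lowest to highest score. It fell and then rose, which a single rho does not show.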

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

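The look at these peaks was chosen after their number had been seen. The comparison of chromosomes left out 8 TBX5 peaks on Y and on random or unplaced contigs. They are given because they lie outside that comparison, and no number of peaks was expected there, so nothing was tested. They held 11 to 40 TBX5 fragments over control levels of 1.18 to 8, with folds of 3.52 to 8.05, and the peak on Y from 257011 to 257177 had the highest of these folds.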

How the results depend on the processing

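The use of the count per gene for the gap to X was chosen after the data were seen. So were the values with the missing peak numbers and with placement within 1 Mb windows or over autosomes alone. The values of the control level and of the relations with score and width were chosen then too. Of 27 alternatives, 14 stayed within limits that differ by kind of value, 12 moved the value and 1 turned its sign. The limits were a factor of 1.5 for a count, the 95% interval of the main value for a median, share or the gap to X, and the direction and side of the threshold for a test, so a small shift of a median is among the 12 and a larger one of a count is not. Most moves follow from the alternative's construction. The higher-scoring part of the list held 4437 peaks with a median width of 255 bp, a median fold of 7.69 and a median −log10 q of 16.1. Merging peaks within 1 kb gave 8351 peaks with a median width of 207 bp, a median fold of 5.56 and a median −log10 q of 8.475. The gap between the lowest autosome and X was 5.44-fold in the higher-scoring peaks and 2.48-fold per protein-coding gene, and 4.40-fold with the missing peak numbers added. With placement over autosomes alone, 6 autosomes in place of 8 held more peaks than placed and 5 in place of 2 held fewer. Both placements treat grouped peaks as independent, so these numbers may be too high. The number of groups of 3 or more fell to 168 at a stitching distance of 5 kb and to 90 in the higher-scoring peaks. These were 51.9 and 36.1 times the number placed over whole chromosomes, and at 5 kb 10.2 times the number placed within 1 Mb windows, so the excess kept its direction but not its size. The relation with clustering was rho = 0.036 by score and 0.088 by width. The share of peaks at a control level of 3 or more was 64.5% with a single solution and 64.1% in the higher-scoring peaks. Ranking by width in place of score turned the relation with the control level to rho = 0.17, and the cause was not tested. The settings planned for 4 results were not run (peak position relative to genes, gene lists, list against list, motifs), which need an mm9 genome. Leaving out a replicate was not possible in a merged list, and no paired analysis was possible because there is a single list. The weak end is set by the q threshold over the local control level. The shallowest peak in the list held 9 TBX5 fragments, but a peak of 56 fragments over a control level of 23 had a −log10 q of only 1.48. Sites below the threshold are not in the list, and the effect of depth was not tested.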

Other observations

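The tests in this part were chosen after the peak numbers, control levels and fragment numbers had been seen, and for X the comparison of strong peaks and the stricter of both thresholds were added after a first thinning result, and the count of X at that threshold later still. The simulated share for broad regions took the place of a fixed limit that did not allow for the way the highest window is chosen.

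Behind the 5 largest groups came 5 groups of 8 TBX5 peaks, and 3 of these held a site of higher fold than any in the 5 largest. The group on chromosome 9 from 119378723 to 119407025 had up to 210 TBX5 fragments at a summit, over control levels up to 10. The group on chromosome 16 from 96421931 to 96451164 reached 176 fragments and a fold of 23.2, and the group on chromosome 5 from 30876839 to 30916882 reached 164 fragments and a fold of 21.7.

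Chromosome X had fewer TBX5 peaks than any autosome, and its peaks had 1.75 control fragments per position in the median against 3.5 on the autosomes; the labels are silent on the sex of the mice, 1 peak on Y may come from male DNA, and a single X per cell would lower both. That alone does not account for the gap: autosomal sites of 60 or more fragments would on average show 30 or more on a single copy. X had 31 peaks of 30 or more fragments (95% Poisson interval 21.1 to 44.0) where the lowest autosome, chromosome 13, predicts 51.6 by span. The counting error of the predictions was not included. Autosomal peaks thinned to 50% predicted 155 or more by span at a −log10 p of 8.31, where X had 76 (59.9 to 95.1). The thinning redrew only the control window that had set each level and left out the others. Its control levels may thus be too low, and the predictions from thinned peaks, here and below, too high by an unknown amount. Fewer genes alone do not either, since the lowest autosome per gene, chromosome 7, predicts 253 peaks on X and 102 were seen. A single copy together with fewer genes may account for it, because chromosome 7 then predicts 32.4 strong peaks, inside the interval, while the other 18 autosomes lie above it. Thinning all autosomal peaks to 50% went against it at the lowest −log10 p in the list (4.22), where the lowest prediction by genes was 187 for the 102 seen, but not at 8.31, where X had 76 peaks (59.9 to 95.1) and chromosome 7 predicts 89.4 (the other 18 autosomes 119 or more), and a lower share of uniquely mapped sequence or truly fewer TBX5 sites on X were not tested.

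The control level at TBX5 sites was higher than evenly spread control reads would give. Taking the highest of several windows of such reads does not account for it. Peaks exceeded evenly covered sites by 52.7 percentage points in reaching a control level of 3. Control levels outside the peaks were not available, so whether control fragments were raised at TBX5 sites in particular was not tested. Broad regions of high control coverage stay open: the 10 kb average set the level at 6.92% of the 8090 peaks above the background (95% Wilson interval 6.39 to 7.50), below the 22.1% or more of evenly raised regions simulated at 10 levels, but unevenly raised regions were not simulated. Another open hypothesis is that these sites lie in chromatin that shears or precipitates well with any antibody, or that some control signal follows sequence composition, and no test of these or of a biological explanation was run.

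The fragment numbers may be compressed at the top of the list. If each read start on each strand counts once, a fragment length of 125 bp allows at most 250 fragments at a summit, and 0 peaks were above that. The 310 peaks beyond 100 fragments had a mean excess of 33.1, and an exponential tail of that slope predicts 3.4 peaks above 250. The slope came from these same counts, so the 3.4 is not an independent prediction, and 0 against 3.4 was not tested. The treatment of duplicates is not given in the sources used here, and the prediction rests on the assumed tail, so a tail that ends sooner for another reason stays open. Under that limit, and with read starts spread evenly over the 250 allowed, the 230 fragments of the deepest peak would stand for 631 before collapse, 2.75-fold more. The 32 of a median peak would stand for 34.2. The even spread was assumed and not tested. Under the limit, folds of the strongest sites would be lower bounds and their order uncertain.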
